A study of Mus musculus with 8 samples.

How the data were processed

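Gene expression was measured on 8 arrays, 2 in each of 4 groups, in the 7438 line. It is a mouse mammary cell line engineered to carry a green fluorescent glucocorticoid receptor and a cherry fluorescent estrogen receptor, both switched on by withdrawing tetracycline. Cells held in hormone-depleted serum were left untreated, given 100 nM of the synthetic glucocorticoid dexamethasone (Dex), given 100 nM estradiol (E2), or given both hormones (Dex+E2), and RNA was taken after 2 hours. Groups and replicate numbers came from the sample titles. The titles call the arrays replicates 1 and 2, but no label used here says that they came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The free-text descriptions of E2 replicate 2 and Dex+E2 replicate 1 name another kind of experiment, while their titles and treatment labels place them in the expression groups used here.

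The deposited table holds log2 values for 45101 probe sets of an Affymetrix mouse array on each of 8 columns. Per the submitters' processing notes, they were made with robust multi-array averaging (RMA) in Affymetrix Expression Console, for which no version is given. RMA subtracts background, equalises the distributions of the arrays and combines the probes of a probe set, so absolute levels of different probe sets are not comparable and changes of dim probe sets are compressed. The arrays' median log2 values ran from 5.58 to 5.67 and their upper quartiles from 7.74 to 7.89. Every column was matched to its sample by name. The number of arrays limits the precision: the median standard error of a difference between 2 groups was 0.0964 on the log2 scale.

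Probe sets were named from the platform annotation supplied with the series, in which 34958 probe sets have 1 gene symbol, 932 have several and 9211 are not listed. Of those with 1 symbol, 34754 matched the RefSeq gene table (mouse assembly GRCm38.p6, used for names only) by Entrez gene number, and 0 symbols changed. Probe sets with several symbols or none were left out of the gene-level tests. A gene was represented by its probe set with the highest mean over all arrays, which gave 18194 genes, of which 9012 have more than 1 probe set.

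The log2 values were fitted with limma (version 3.58.1 in R 4.3.3) as 4 group means on all 8 arrays, with 4 residual degrees of freedom and 6.2 prior degrees of freedom from empirical Bayes moderation. The comparisons were each treatment against untreated, Dex+E2 against Dex and against E2, the Dex by E2 interaction (the Dex effect with E2 minus the Dex effect without it), and the mean effect of each hormone over both states of the other. P-values were adjusted with the Benjamini-Hochberg method over the genes tested, and a gene was called changed at an adjusted p under 0.05. Errors given after ± are standard errors from limma for differences and standard deviations for group levels.

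The gene lists were fixed before the data were examined: glucocorticoid targets, estrogen targets, inflammatory genes, immediate early genes, MAPK feedback regulators, circadian clock genes, cell cycle genes, TGF-beta/SRF/YAP targets, stress genes, sterol and lipid genes, epithelial, mesenchymal, milk protein, immune cell and endothelial or adipose markers, and hormone receptors, of which the last was described by values only. The other 15 lists were tested with limma's camera at its preset inter-gene correlation of 0.01 and adjusted over the 15 lists within a comparison. Alternatives were the correlation estimated from the residuals, and fry. The estimated setting alters the test beyond the correlation, since it also raised p-values of some lists whose estimate lay below 0.01. The 10 list genes that no probe set with 1 symbol names are not analysed here.

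Genes named in the text follow a rule set before the data were examined. For each comparison with untreated they are up to 12 higher and 8 lower genes with the largest change among those past the threshold whose arrays do not overlap between the groups, leaving out predicted and clone names, up to 4 past the threshold from each list, and 9 genes that are always given (Fkbp5, Per1, Tsc22d3, Sgk1, Lcn2, Greb1, Pgr, Nr3c1 and Esr1). Where under 10 genes passed, the 5 higher and 5 lower genes with the smallest p-value are given as not past the threshold. Genes outside this rule are marked as chosen after their values were seen.

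Slopes through the origin set the effect of one hormone in the presence of the other against its effect alone, over the genes past the threshold for that hormone's mean effect; the 2 axes share no array. The Dex and E2 comparisons share the untreated arrays, so their overlap was set beside 100 simulations of unchanged groups against those arrays and beside the product of both counts over the genes tested.

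The gene-level script was tested on simulated arrays with the real means and spreads of 18194 genes and 200 changed genes. For Dex against untreated it recovered 49.3% of genes changed by 0.5 on the log2 scale, 98.5% of those changed by 1 and 100% of those changed by 2. For the interaction these shares were 5.97%, 86.6% and 100%. A first version of this test drew spreads that were too even between genes and was replaced after its output was seen.

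Alternatives were the replicate number as a block, the mean of a gene's probe sets, every row of the table tested separately, leaving out genes under the 40th percentile of mean level, a trended and robust prior, a second quantile normalization, array weights, a minimum fold of 1.5, the 4 arrays of a comparison alone, a 2-group model for the mean effects, and leaving out each array in turn. List tests without Dex+E2 replicate 2, list tests with an estimated correlation and dim genes left out, the E2 changes of Dex-lower genes with the untreated arrays split, a block with the Dex+E2 replicate numbers crossed, a direct comparison of E2 with Dex, the mean of probe sets for the mean Dex effect on Nr3c1 and a test of 1 share of Dex RNA over the 13 genes called higher with both hormones were added after seeing the data.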

Results

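The 8 arrays covered untreated 7438 cells and cells given Dex, E2 or both for 2 hours, with 2 arrays in each group. The design asks how co-treatment with 2 steroid hormones alters the transcriptional response to each of them, in cells that carry both receptors. The pairs of replicate arrays correlated at 0.998 for untreated cells, 0.999 for Dex, 0.998 for E2 and 0.997 for Dex+E2. The standard deviation over genes of the difference between replicates was 0.156, 0.132, 0.159 and 0.197 in that order, and 390 genes differed by over 0.5 log2 units between the Dex+E2 arrays, against 19 to 95 in the other groups. Dex+E2 replicate 2 had the lowest mean correlation with the other arrays, 0.9959.

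Among the hormone receptor genes, Nr3c1, which encodes the glucocorticoid receptor, had a mean log2 signal of 9.96 ± 0.0084 (SD, n = 2) in untreated cells and Esr1, which encodes estrogen receptor alpha, 6.99 ± 0.095. The Nr3c1 difference with Dex was -0.47 log2 units and did not pass the threshold (limma, Benjamini-Hochberg adjusted p = 0.114). Its mean Dex effect over both E2 states, named after its value was seen, was -0.46 and passed (limma, Benjamini-Hochberg adjusted p = 0.0149). That pass rests on the probe set used: with the mean of the gene's probe sets the 2 values were -0.20 (adjusted p = 0.853) and -0.28 (adjusted p = 0.0804), and neither passed. Over 16 other settings, that mean included, the Dex difference passed in 5, with the lowest adjusted p, 0.0166, without either Dex+E2 array. Esr1 differed from untreated by 0.09 with Dex, -0.08 with E2 and 0.20 with both. The probe sets of Pgr, the progesterone receptor, Esr2, estrogen receptor beta, and Nr3c2, the mineralocorticoid receptor, lay at 4.33, 4.53 and 4.63 in untreated cells, and none of them passed the threshold in a comparison with untreated. Whether these probe sets read the transgenes was not tested.

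Dex alone raised textbook glucocorticoid targets within 2 hours. Rgs2, a regulator of G-protein signalling, rose by 3.21 ± 0.22 log2 units (9.23-fold), Tsc22d3, the glucocorticoid-induced leucine zipper, by 2.82 ± 0.23, and the clock gene Per1 by 2.66 ± 0.13. Dusp1, a phosphatase that inactivates MAP kinases, rose by 2.54 ± 0.14 and Fkbp5, an Hsp90 co-chaperone that limits receptor signalling, by 1.62 ± 0.11. Genes outside the glucocorticoid list rose as far. Among them were Sphk1, sphingosine kinase, up by 3.16 ± 0.13, and Spsb1, a substrate adaptor of ubiquitin ligases, up by 2.95 ± 0.10. Fabp4, a fatty acid carrier, rose by 2.65 ± 0.34, Suox, sulfite oxidase, by 2.52 ± 0.14 and F3, tissue factor, by 2.51 ± 0.23. The acute-phase gene Orm1 rose by 2.26 ± 0.22 and Il6ra, the interleukin 6 receptor, by 2.21 ± 0.15. Apart from Ankrd1 and Thbs1, which belong to the TGF-beta/SRF/YAP list, the deepest falls were in Klf10, a TGF-beta-inducible transcription factor, -1.93 ± 0.15, the neurotrophic factor gene Gdnf, -1.88 ± 0.14, the aryl hydrocarbon receptor gene Ahr, -1.85 ± 0.10, Phlda1, -1.71 ± 0.096, the chemokine gene Cxcl3, -1.57 ± 0.25, and Artn, another neurotrophic factor of the Gdnf family, -1.51 ± 0.14.

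In all, limma called 267 of 18194 genes changed with Dex at a Benjamini-Hochberg adjusted p under 0.05, 157 higher and 110 lower, and 63 and 27 of these changed at least 2-fold. The count was 156 without untreated replicate 1, 144 without untreated replicate 2, 131 without Dex replicate 1 and 157 without Dex replicate 2, so each array of the comparison moved it by over 1.5 times. Among the named genes, 5 to 9 lost the call when any of these 4 arrays was left out, with adjusted p from 0.0506 to 0.332. Chac1, Cxcl3, Fos, Irf1 and Nrip1 lost it without each of the 4, Ddit3 and Insig1 without 3 of them, Per2 without untreated replicate 2 or Dex replicate 1, and Herpud1 without Dex replicate 1. With the mean of a gene's probe sets, Per2 was 0.32 higher (limma, Benjamini-Hochberg adjusted p = 0.114) and Nrip1 0.32 (0.135), and both lost the call. With every probe set tested separately, Chac1 (adjusted p = 0.0527) and Nrip1 (0.0704) lost it.

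**Figure D1:**
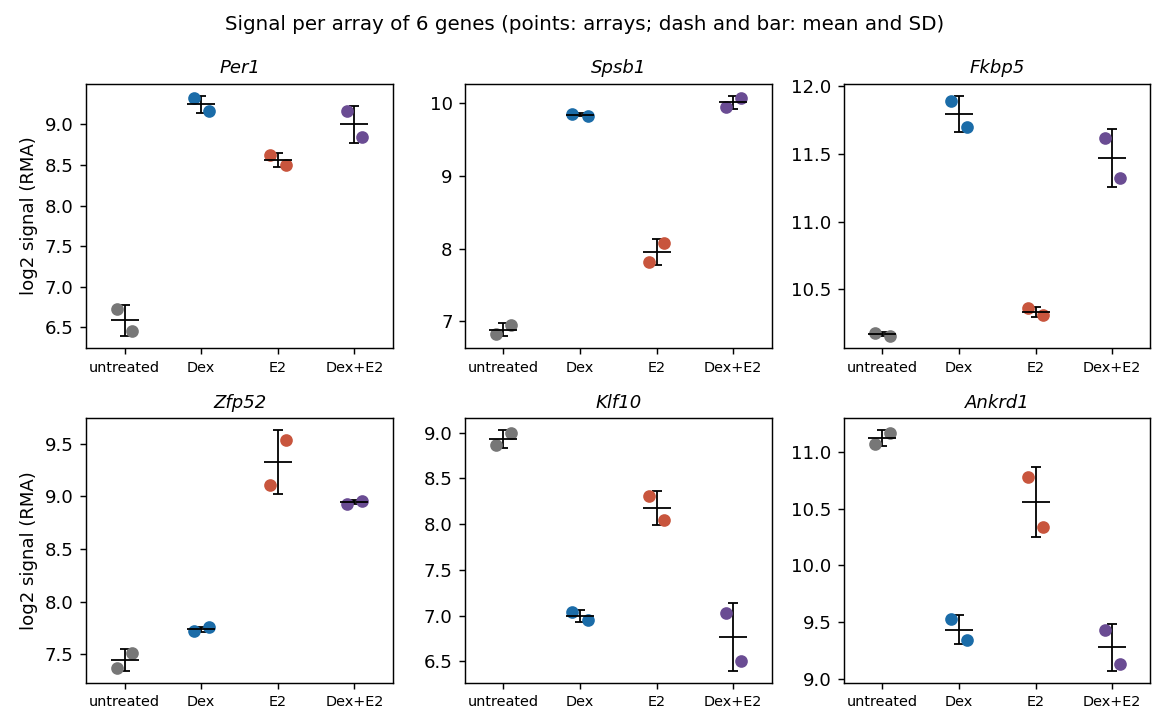
Log2 RMA signal of 6 genes on each of the 8 arrays, by group, with each group's mean and SD; vertical scales differ between genes and do not start at 0. Per1 stood at 6.59 in untreated cells and 9.24, 8.56 and 9.0 with Dex, E2 and both, while the Zfp52 means with E2 and with both, 9.32 and 8.94, lay above the 7.74 with Dex.

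Of the 27 measured glucocorticoid targets, 19 rose with Dex, 0 fell and 8 did not pass, with a median change of 1.31 log2 units and 21 changed when adjusted over the list alone. Sgk1, a serum- and glucocorticoid-regulated kinase, rose by 1.31 ± 0.14 and Lcn2, the secreted siderophore binder lipocalin 2, by 2.00 ± 0.17. The camera adjusted p was 2.75e-51, and the call held at 0.00745 with an estimated correlation. It was the only one of 8 camera calls for Dex that held under that setting. The list of circadian clock genes had 3 of 18 members higher and 0 lower (4 changed when adjusted over the list alone, 2 members lower at an unadjusted limma p under 0.05), namely Per1, the clock output repressor Nfil3, 1.27 ± 0.13, and Per2, 0.81 ± 0.11. As a list it did not pass camera (adjusted p = 0.148).

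Inflammatory genes fell in part: 3 of 26 members were lower and 0 higher with Dex (4 changed when adjusted over the list alone, 2 members higher at an unadjusted limma p under 0.05). They were Plau, the urokinase-type plasminogen activator, -1.37 ± 0.15, Csf1, a macrophage growth factor, -1.15 ± 0.11, and the interferon-responsive factor Irf1, -0.64 ± 0.11. Camera placed the list lower (adjusted p = 0.000442), a call lost at adjusted p = 0.269 with an estimated correlation. Immediate early genes split, with 2 of 18 higher and 3 lower (12 changed when adjusted over the list alone): the AP-1 family genes Maff and Fos rose by 1.55 ± 0.14 and 1.2 ± 0.21, while Fosl2 fell by 1.41 ± 0.14 and the stress-response gene Ier3 fell by 1.04 ± 0.10. Their camera adjusted p was 0.00396, lower, and 0.195 as adjusted p with an estimated correlation.

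MAPK feedback regulators also moved both ways, 2 of 14 higher and 3 lower (7 changed when adjusted over the list alone). Errfi1, an inhibitor of the EGF receptor, rose by 1.98 ± 0.11 beside Dusp1, while Dusp4 fell by 1.22 ± 0.087 and Dusp10 fell by 0.62 ± 0.082. Their median was -0.08, their mean 0.14 and the camera direction lower, without passing (adjusted p = 0.378). Of 17 TGF-beta/SRF/YAP targets 1 rose and 3 fell (7 changed when adjusted over the list alone). Ccn2, a matricellular growth factor, rose by 2.51 ± 0.27, while the nuclear cofactor gene Ankrd1 fell by 1.69 ± 0.15, the matrix glycoprotein gene Thbs1 fell by 1.51 ± 0.12 and the inhibitory Smad gene Smad7 fell by 0.78 ± 0.091. Camera gave this list adjusted p = 0.0356, lower, which became 0.0724 without Dex+E2 replicate 2 and was lost at adjusted p = 0.195 with an estimated correlation.

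Of 14 stress genes, the endoplasmic reticulum protein gene Herpud1 rose by 0.80 ± 0.11 with Dex, while Ddit3 and Chac1, both of the integrated stress response, fell by 0.58 ± 0.098 and 0.48 ± 0.092 (4 changed when adjusted over the list alone; camera adjusted p = 0.0138, lower, and adjusted p = 0.443 with an estimated correlation). Insig1, a brake on sterol synthesis, was the 1 sterol and lipid gene of 12 to change, -0.57 ± 0.10 (also 1 adjusted over the list alone; camera adjusted p = 0.00919, lower, and adjusted p = 0.178 with an estimated correlation). Snai2, a transcription factor of mesenchymal cells, was the 1 of 14 mesenchymal genes past the threshold, -1.10 ± 0.11, against 5 when adjusted over the list alone (camera adjusted p = 1.54e-05, lower, and adjusted p = 0.132 with an estimated correlation). Among 29 estrogen targets, Zfp36l2, an mRNA decay factor, rose by 1.37 ± 0.12 and Nrip1, a nuclear receptor corepressor, by 0.48 ± 0.098 (3 changed when adjusted over the list alone; camera adjusted p = 0.378).

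Cell cycle, epithelial, milk protein and immune cell lists held 0 genes past the threshold with Dex in limma, with 1, 2, 1 and 0 members at an unadjusted p under 0.05, and 0 were changed when adjusted over each list alone. The cell cycle list nonetheless passed camera, lower with a median of -0.05 (adjusted p = 0.0315, and adjusted p = 0.582 with an estimated correlation), while the epithelial (0.891), milk protein (0.290) and immune cell (0.891) lists did not. The epithelial median and test lay below 0 and its mean above. Fabp4 was the 1 of 7 endothelial or adipose markers that rose (2 changed when adjusted over the list alone; median -0.09, mean 0.21, camera adjusted p = 0.580).

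E2 alone changed far fewer genes, and most of those it raised also rose with Dex. Per1 rose by 1.97 ± 0.13 log2 units (3.92-fold), the arrestin-domain gene Arrdc2 by 1.61 ± 0.19 and Sphk1 by 1.27 ± 0.13. Cdkn1a, the cyclin-dependent kinase inhibitor p21, rose by 1.21 ± 0.14, Per2 by 1.16 ± 0.11, Il6ra by 1.14 ± 0.15. The lipid droplet gene Plin4 rose by 1.08 ± 0.10, Spsb1 by 1.06 ± 0.10 and Pdk4, a kinase that restrains pyruvate oxidation, by 1.05 ± 0.15. The 3 others among the 12 largest rises were not called with Dex: the zinc finger gene Zfp52 rose by 1.88 ± 0.13, Tmem86a, an enzyme of ether lipid turnover, by 1.71 ± 0.18, and Ttpa, the vitamin E transfer protein, by 1.71 ± 0.25. Of the estrogen-responsive genes that are always given, neither Greb1, 0.04 ± 0.10 log2 units from untreated, nor Pgr, -0.0024 ± 0.11, passed. The Pgr probe set is dim (percentile 16.6 of mean level), so little can be read from it. With the mean of its probe sets Greb1 was at 0.28, without passing (limma, Benjamini-Hochberg adjusted p = 0.524).

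Limma called 19 of 18194 genes changed with E2 at a Benjamini-Hochberg adjusted p under 0.05, 19 higher and 0 lower, against 645 higher and 479 lower at an unadjusted p under 0.05. With a trended and robust prior the count was 35, with 2 lower. It was 3 without untreated replicate 1, 2 without untreated replicate 2, 11 without either Dex array, 37 without E2 replicate 1, 2 without E2 replicate 2 and 34 without either Dex+E2 array. Of the named genes, Per1 and Zfp52 kept the call without each array in turn. The other 11 lost it without untreated replicate 2 or without E2 replicate 2, and all of them but Per2 without untreated replicate 1, with adjusted p from 0.0511 to 0.531. Il6ra, Pdk4 and Ttpa also lost it without either Dex array (adjusted p 0.0785 to 0.123), and Pdk4 without E2 replicate 1 (0.0577). With the mean of a gene's probe sets, Spsb1 was 0.39 higher (adjusted p = 0.233) and Il6ra 0.54 (adjusted p = 0.101), and both lost the call. With every probe set tested separately, Pdk4 (adjusted p = 0.0634) and Ttpa (0.0711) lost it.

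Of the 27 glucocorticoid targets, 5 rose with E2 and 0 fell, namely Per1, Cdkn1a, Pdk4, Errfi1 (0.95 ± 0.11) and, named after its value was seen, the transcription factor gene Klf9 (0.88), and 11 were changed when adjusted over the list alone. The other targets that are always given did not pass: Tsc22d3 was 0.97 ± 0.23, Sgk1 0.46 ± 0.14, Fkbp5 0.16 ± 0.11 and Lcn2 0.10 ± 0.17 above untreated. The list's median was 0.16, and camera placed it higher at adjusted p = 1.62e-12, a call lost at adjusted p = 0.111 with an estimated correlation. Circadian clock genes had Per1 and Per2 higher among 18 (4 changed when adjusted over the list alone; camera adjusted p = 0.00271, higher, and adjusted p = 0.138 with an estimated correlation).

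None of the 29 estrogen targets passed with E2 in limma (5 at an unadjusted p under 0.05, 3 changed when adjusted over the list alone). Their median was -0.02, their mean 0.01 and the camera direction higher, at adjusted p = 0.806. Inflammatory genes had 0 of 26 past the threshold (5 unadjusted, 2 changed when adjusted over the list alone) and a median of -0.10, with camera adjusted p = 0.00271, lower, and adjusted p = 0.459 with an estimated correlation. Errfi1 was the 1 of 14 MAPK feedback genes that rose (2 changed when adjusted over the list alone). The immediate early, TGF-beta/SRF/YAP, stress, cell cycle, sterol and lipid, epithelial, mesenchymal, milk protein, immune cell and endothelial or adipose lists held 0 genes past the threshold, with 6, 8, 2, 4, 1, 2, 0, 3, 0 and 0 at an unadjusted limma p under 0.05 and 4, 5, 2, 0, 0, 0, 0, 2, 0 and 0 changed when adjusted over the list alone. None of these lists or the MAPK list passed camera with E2, with adjusted p from 0.0596 to 0.806.

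**Figure D2:**
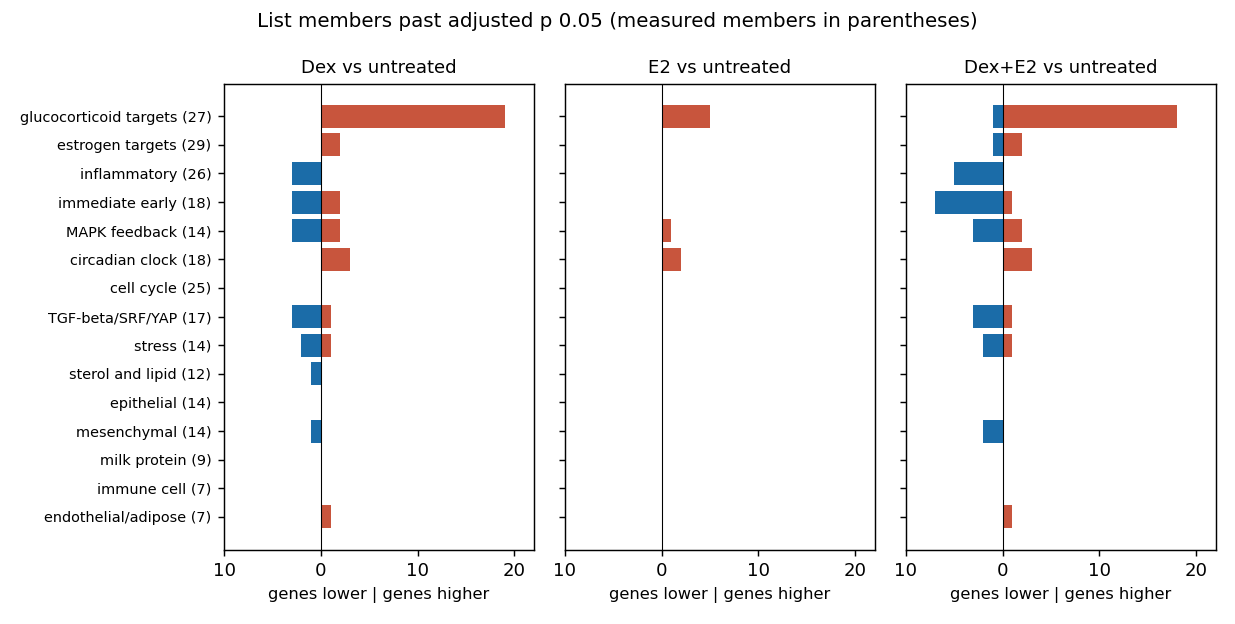
Number of genes past an adjusted p of 0.05 in each list, lower to the left of 0 and higher to the right, for each treatment against untreated, with the measured members in parentheses. Glucocorticoid targets had 19 higher with Dex, 5 with E2 and 18 with both, and the inflammatory list had 3, 0 and 5 lower.

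The Dex and E2 calls shared 14 genes, 13 of them higher with both hormones. Lists of these sizes drawn independently would share 0.164 higher genes. Simulated unchanged groups compared with shared, also simulated, untreated arrays had a mean of 0.03 genes in common. Those groups gave a mean of 0.30 calls for Dex and 0.32 for E2, so they could share almost none and say little about the 13. The remaining shared gene, Bnc1, a transcription factor of epithelial cells named after its values were seen, rose by 0.97 ± 0.13 with E2 and fell by 0.64 ± 0.13 with Dex. The shared number was 2 without untreated replicate 1, 1 without untreated replicate 2, 8 and 9 without Dex replicates 1 and 2, 1 without E2 replicate 2 and 24 without either Dex+E2 array. Over all genes the changes with Dex and E2 correlated at 0.431, against 0.50 in the simulations, and their covariance was 0.0101 against 0.00547, a difference of 0.00466. With Dex taken against 1 untreated array and E2 against the other, the correlations were 0.208 and 0.0728 and the covariances 0.00579 and 0.00231. Each side then rests on 1 array, and part of the excess in the shared calls may come from the shared untreated arrays.

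Of the 157 genes higher with Dex, the 13 shared calls included, 132 were above 0 with E2, with a median of 0.19. Of the 110 lower with Dex, 92 were below 0, with a median of -0.24. The shared untreated arrays alone pull such values to the same side. With the genes picked against 1 untreated array and the E2 change taken against the other, the medians were 0.23 and 0.26 for 98 and 96 higher genes and -0.32 and -0.22 for 46 and 60 lower genes. Random lists matched on level had medians up to 0.05 and 0.10 for the former and down to -0.10 and -0.06 for the latter.

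With both hormones the profile resembled that of Dex in its leading genes. Spsb1 rose by 3.12 ± 0.10 log2 units (8.68-fold), Sphk1 by 2.94 ± 0.13, Per1 by 2.41 ± 0.13, and Rgs2 by 2.33 ± 0.22. The mRNA decay factor gene Zfp36 rose by 2.32 ± 0.16, Suox by 2.27 ± 0.14, Tsc22d3 by 2.26 ± 0.23, Arrdc2 by 2.23 ± 0.19 and Dusp1 by 2.23 ± 0.14. Cdkn1a rose by 2.18 ± 0.14, Ccn2 by 2.09 ± 0.27 and Il6ra by 2.08 ± 0.15. Klf10 fell by 2.16 ± 0.15, Ankrd1 fell by 1.84 ± 0.15, Phlda1 fell by 1.82 ± 0.096 and Cxcl3 fell by 1.79 ± 0.25. Ptx3, a secreted pattern-recognition protein, fell by 1.77 ± 0.20, Gdnf fell by 1.77 ± 0.14, the polo-like kinase gene Plk2 fell by 1.76 ± 0.20 and Ahr fell by 1.63 ± 0.10. Zfp52, Tmem86a and Ttpa, called with E2 and not with Dex, were also higher with both, by 1.5 ± 0.13, 1.25 ± 0.18 and 1.37 ± 0.25.

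Limma called 265 genes changed with Dex+E2 at a Benjamini-Hochberg adjusted p under 0.05, 146 higher and 119 lower, of which 196 were also called with Dex, all in the same direction, and 16 with E2. The count was 128 without untreated replicate 1, 114 without untreated replicate 2 and 608 without Dex+E2 replicate 1. Without Dex+E2 replicate 2, the array that stood apart, it was 201, and with only the 4 arrays compared it was 171. Named genes lost the call most often without untreated replicate 2 (12 genes) or replicate 1 (11 genes), 8 lost it without Dex+E2 replicate 2, 7 without either Dex array, 2 without Dex+E2 replicate 1 and 1, Ddit3, without either E2 array, with adjusted p from 0.0501 to 0.385. Those concerned were Ccn2, Chac1, Cxcl3, Cxcl5, Ddit3, Dusp10, Fabp4, Lcn2, Maff, Myc, Nrip1, Ptgs2, Smad7 and Twist1. With the mean of a gene's probe sets, Plk2 was at -0.74 (adjusted p = 0.0791), Dusp10 at -0.31 (0.0799) and Nrip1 at 0.34 (0.102), and these lost the call. With every probe set tested separately, Myc (adjusted p = 0.0550) and Ddit3 (0.0649) lost it, and Ddit3 also with array weights (0.0733). The other Plk2 probe set was 0.27 log2 units above untreated, and those of Ptx3 and Plau lay 0.01 and 0.06 above it. With the mean, Ptx3 was at -0.88, Plau at -0.68 and Ahr at -0.83, and these kept the call.

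Among glucocorticoid targets 18 of 27 rose with both hormones, 1 fell and 8 did not pass (21 changed when adjusted over the list alone), with a median of 1.05. Fkbp5 rose by 1.30 ± 0.11, Sgk1 by 1.10 ± 0.14 and Lcn2 by 1.11 ± 0.17, while Angptl4, an inhibitor of lipoprotein lipase named after its value was seen, fell by 0.99 ± 0.19. The camera adjusted p was 9.22e-37 and held at 0.0143 with an estimated correlation. Clock genes had Per1, Per2 (1.18 ± 0.11) and Nfil3 (1.06 ± 0.13) higher of 18 (3 changed when adjusted over the list alone; camera adjusted p = 0.0264, higher, and adjusted p = 0.156 with an estimated correlation).

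Inflammatory genes had 5 of 26 lower and 0 higher with both hormones (7 changed when adjusted over the list alone): Plau, -1.42 ± 0.15, Csf1, -1.0 ± 0.11, the neutrophil chemokine gene Cxcl5, -0.93 ± 0.18, Ptgs2, the inducible cyclooxygenase, -0.75 ± 0.14, and Irf1, -0.71 ± 0.11. Immediate early genes had 7 of 18 lower and 1 higher (13 changed when adjusted over the list alone), among them Ier3, -1.28 ± 0.10, Fosl2, -1.22 ± 0.14, the growth regulator Myc, -0.99 ± 0.20, and Maff, 0.95 ± 0.14. Mesenchymal genes had 2 of 14 lower (3 changed when adjusted over the list alone), Snai2, -1.08 ± 0.11, and Twist1, -0.47 ± 0.086. Camera placed all 3 lists lower (adjusted p = 1.69e-06, 0.00175 and 0.000309), and each was lost at adjusted p = 0.156 with an estimated correlation. With fry, which does not compare a list with other genes, they were lower at adjusted p = 0.0287, 0.0176 and 0.0178. The 3 lists kept their camera calls without Dex+E2 replicate 2.

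MAPK feedback genes had 2 of 14 higher and 3 lower with both hormones (7 changed when adjusted over the list alone; median -0.08, mean 0.06), with Errfi1 up by 1.93 ± 0.11, Dusp4 at -0.95 ± 0.087 and Dusp10 at -0.60 ± 0.082. Stress genes had Herpud1 higher, 1.00 ± 0.11, and Chac1 and Ddit3 lower, -0.53 ± 0.092 and -0.49 ± 0.098 (3 changed when adjusted over the list alone), and the 25 cell cycle genes had 0 changed in limma over all genes or over the list alone (2 at an unadjusted p under 0.05), with a median of -0.09. These 3 lists passed camera as lower (adjusted p = 0.0299, 0.0208 and 0.00137), with adjusted p = 0.156, 0.448 and 0.448 with an estimated correlation, and each lost the call without Dex+E2 replicate 2 (adjusted p = 0.236, 0.183 and 0.529).

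TGF-beta/SRF/YAP targets had Ccn2 higher and Ankrd1, Thbs1 (-1.21 ± 0.12) and Smad7 (-0.60 ± 0.091) lower of 17 with both hormones (9 changed when adjusted over the list alone; median 0.01, mean -0.06, camera lower at adjusted p = 0.282). Estrogen targets had Zfp36l2 (1.24 ± 0.12) and Nrip1 (0.60 ± 0.098) higher and Myc lower of 29 (5 changed when adjusted over the list alone; camera adjusted p = 0.413), with Greb1 at 0.12 ± 0.10 and Pgr at 0.09 ± 0.11. With the mean of its probe sets Greb1 was at 0.57 and passed (limma, Benjamini-Hochberg adjusted p = 0.00545), so its call depends on the probe set. Fabp4, 1.81 ± 0.34, was the 1 endothelial or adipose marker that rose (camera adjusted p = 0.826 for the list). The Dex+E2 arrays differed widely for Fabp4, with an SD of 1.03 log2 units. Sterol and lipid, epithelial, milk protein and immune cell lists had 0 genes past the threshold in limma, 1, 1, 1 and 2 at an unadjusted p under 0.05, 1, 0, 0 and 0 changed when adjusted over the list alone, and camera adjusted p of 0.196, 0.413, 0.826 and 0.537. The milk protein median, 0.04, and mean, 0.02, lay above 0 while the camera direction was lower.

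Adding E2 to Dex changed 2 genes against Dex alone, Tmem86a, which rose by 1.72 ± 0.18, and Zfp52, which rose by 1.21 ± 0.13 (limma, Benjamini-Hochberg adjusted p = 0.0184 for both). At an unadjusted p under 0.05 there were 469 genes higher and 380 lower, where 910 would be expected by chance. The count was 0 without either untreated array or either Dex array, 4 without either E2 array, 81 without Dex+E2 replicate 1 and 1 without Dex+E2 replicate 2. Glucocorticoid targets had a median of -0.15 against Dex alone with 0 of 27 members past the threshold (2 changed when adjusted over the list alone), camera adjusted p = 2.77e-05, lower, and adjusted p = 0.484 with an estimated correlation.

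Adding Dex to E2 changed 114 genes against E2 alone, 64 higher and 50 lower, at a Benjamini-Hochberg adjusted p under 0.05 in limma. Rgs2 was 2.12 ± 0.22, Spsb1 2.05 ± 0.10, Dusp1 1.99 ± 0.14, Sphk1 1.67 ± 0.13, Suox 1.61 ± 0.14 and Fkbp5 1.13 ± 0.11 log2 units higher, while Klf10 fell by 1.40 ± 0.15, Ankrd1 fell by 1.28 ± 0.15, Gdnf fell by 1.25 ± 0.14 and Phlda1 fell by 1.24 ± 0.096. Of 27 glucocorticoid targets 11 rose (20 changed when adjusted over the list alone; camera adjusted p = 3.62e-20, and 0.0456 with an estimated correlation). Inflammatory, immediate early and mesenchymal genes passed camera as lower (adjusted p = 0.039, 0.0182 and 0.00649), calls lost at adjusted p = 0.570, 0.330 and 0.330 with an estimated correlation. The count was 65 without either untreated array or either Dex array, 31 and 62 without E2 replicates 1 and 2, and 858 without Dex+E2 replicate 1, while without Dex+E2 replicate 2 it was 80. With only the 4 arrays compared it was 23.

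The test of co-treatment itself, whether the Dex effect differed with E2 present, was passed by Per1. Dex raised Per1 by 2.66 ± 0.13 log2 units without E2 and its level with both hormones stood 0.44 above that with E2 alone, an interaction of -2.21 ± 0.18 (limma, Benjamini-Hochberg adjusted p = 0.00348). The call was lost without Dex replicate 1 (adjusted p = 0.063) and kept under the 15 other alternatives tried for it, where the interaction ranged from -2.37 to -2.05. The next genes by p-value did not pass: Sphk1, -1.49 ± 0.19 (adjusted p = 0.0917), Foxred2, -1.48 ± 0.21, Orm3, -0.78 ± 0.11, and Errfi1, -1.0 ± 0.15, below 0, and Ahr, 0.75 ± 0.14, Tex19.1, 0.57 ± 0.13, Arc, 0.63 ± 0.15, Apln, 0.52 ± 0.13, and Nr2e1, 0.62 ± 0.15, above 0. The count of 1 gene became 0 without Dex replicate 1, 2 without E2 replicate 1 and 20 without Dex+E2 replicate 1, and was 4 with a trended and robust prior.

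Glucocorticoid targets as a list lay below 0 in the interaction, with a median of -0.56, 17 of 27 changed when adjusted over the list alone and 1, Per1, over all genes. Of the targets always given, Tsc22d3 was at -1.54 ± 0.33, Lcn2 at -0.99 ± 0.24, Sgk1 at -0.67 ± 0.19 and Fkbp5 at -0.49 ± 0.16, none of them past the threshold over all genes. Camera placed the list lower at adjusted p = 9.71e-19, and that call was lost at adjusted p = 0.0524 with an estimated correlation, while fry, which asks whether the list moved one way and does not compare it with other genes, gave 0.0494. The other 14 lists did not pass camera for the interaction.

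Averaged over both states of the other hormone, Dex changed 404 genes (196 higher, 208 lower) and E2 changed 35 (34 higher and 1 lower, Id3, an inhibitor of differentiation named after its value was seen, -0.83 ± 0.10) at a Benjamini-Hochberg adjusted p under 0.05 in limma. Camera called 7 lists for the mean Dex effect and 4 for the mean E2 effect, of which 1, glucocorticoid targets, and 0 held with an estimated correlation. For the mean Dex effect the largest rises were those of Rgs2, 2.67 ± 0.16, and Spsb1, 2.5 ± 0.073, and the deepest fall was that of Klf10, -1.67 ± 0.11. For the mean E2 effect the largest were those of Tmem86a, 1.72 ± 0.12, Zfp52, 1.54 ± 0.089, and Ttpa, 1.48 ± 0.17. The Dex count was 244 without untreated replicate 2, 239 and 263 without Dex replicates 1 and 2, and 840 without Dex+E2 replicate 1. The E2 count was 5 and 3 without untreated replicates 1 and 2, 5 and 2 without Dex replicates 1 and 2, 58 and 13 without E2 replicates 1 and 2, and 90 without Dex+E2 replicate 1.

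Over the 404 genes, the log2 Dex effect in the presence of E2 was smaller than without it in 329 genes. The slope was 0.606 (jackknife standard error 0.080) and the reverse slope 1.45. Both effects had the same sign in 404 genes, which the choice of genes by the mean of these effects favours. Genes higher with Dex had a slope of 0.557 and genes lower with Dex 0.726. In the 196 higher genes, E2 changed levels by a median of 0.15 without Dex and -0.15 with Dex, so that the median Dex effect was 0.72 without E2 and 0.45 with it. For E2, over 35 genes, the slope of the effect with Dex on the effect without was 0.590 (jackknife standard error 0.129). Its reverse slope was 1.04, and the effect was smaller with Dex in 23 of the 35 genes, so a weaker E2 effect with Dex is not clear. The forward slope was 0.279 in the 17 genes that also passed for the mean Dex effect and 0.876 in the 18 that did not, a contrast that was not tested. The reverse slopes of these groups, 1.035 and 1.036, hardly differed. Genes are not independent replicates, so no p-value is given for the slopes.

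**Figure D3:**
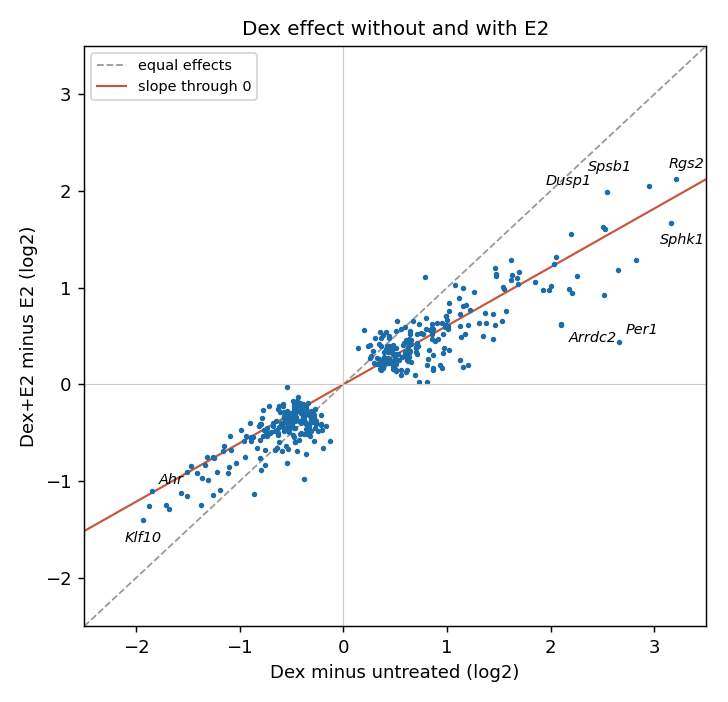
Dex effect without E2 (Dex minus untreated, log2, horizontal) against Dex effect with E2 (Dex+E2 minus E2, log2, vertical) for the 404 genes past the threshold for the mean Dex effect, 1 point per gene, with the line of equal effects and the line of slope 0.606. Per1 lies at 2.66 and 0.44, farther below the line of equal effects than Spsb1 at 2.95 and 2.05.

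Fkbp5 aside, of the 53 named calls on genes with further probe sets, 80 of the 88 other probe sets changed with the same sign, 38 of them by at least 50% as much, and 8 calls had another probe set of opposite sign. With the mean of a gene's probe sets, Fkbp5 included, 31 of 55 named calls had a change over 1.5 times smaller and 7 lost the call, so sizes such as those of Spsb1, 1.37 with Dex by the mean, belong to the probe set used.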

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

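Every test in this part was chosen after values bearing on it had been seen, except the simulated slopes and the counts over other splits of the arrays.

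Per1 differed in its response to Dex between cells without and with E2, with an interaction of -2.21 log2 units in limma. The list of glucocorticoid targets also differed, with a median interaction of -0.56, a call that camera made at its preset correlation and lost with an estimated one (adjusted p = 0.0524). Outside the gene-level tests, 34 of the 9211 probe sets with no listed gene changed with Dex against untreated (20 higher, 14 lower, 0.369%) when every row of the table was tested with limma.

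E2 raised genes that Dex raised, 13 of its 19 calls. Chance values private to each untreated array are argued against. With Dex-higher genes picked against 1 untreated array and the E2 change taken against the other, the medians were 0.23 and 0.26. These lay above the upper limits of the 95% range of random lists matched on level, 0.02 and 0.06. A deviation common to both untreated arrays would pass this split. The random lists were matched on level only, not on how the genes vary together. Whether a single share of RNA of Dex-treated cells in the E2 samples is the whole cause could not be decided. Of the 13 genes, 5 lay over 3 standard errors from the level given by the best share of all 13, 36.7%. Per2, Dnajb4 and Klf9 lay above it, with an implied share of 163% for Per2. Sphk1 and Spsb1 lay below it, with 16.2% for Spsb1. The 13 were picked partly by their E2 change, which favours high values and raises that share. The 2 genes below it therefore do not count against mixing. The 3 genes above it are of the kind that this pick favours, so they do not decide against mixing either. At the best share of the 63 genes raised at least 2-fold by Dex, 15.95%, Sphk1 and Spsb1 lay 0.53 and 0.10 standard errors away. A share of such RNA stays open, alone or beside another effect. Over the 63 genes raised at least 2-fold by Dex, 17.5% lay over 3 standard errors from their best share, 7 above and 4 below. This is on the side of mixing by a 20% limit chosen with the shares of Per1 and Dusp1 known. The 1.31% expected by chance, worked out only after the result, speaks against mixing and moved the reading to undecided. Implied shares of the 63 genes ran from -9.76% to 62.5%. The 4 below, Orm3, Dusp1, Rgs2 and Rhob, implied 5.9%, 3.8%, 1.9% and -1.2%. A share common to all genes would have to be about as low, unless another effect lowered these 4. A small amount of Dex in the E2 cultures cannot be told apart from an effect of E2 on these 13 genes with 1 dose of each hormone: Per2 and Dnajb4 lay higher with E2 than with Dex, but not past the threshold (limma, Benjamini-Hochberg adjusted p = 0.330 and 0.701), and 6 of the 19 calls (Bnc1, Micall1, Pim1, Tmem86a, Ttpa and Zfp52) were not called higher with Dex, while an effect of E2 itself was not tested, as no sample here lacks or blocks a receptor.

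Dex changed its genes less in the presence of E2, with a slope of 0.606 on the log2 scale. On that scale, effects that add in linear signal also look smaller in genes raised by both hormones, which was not tested. Such adding by itself would leave the E2 change with Dex above 0 in those genes. Over the 196 Dex-higher genes, whether raised by E2 or not, the median of that change was -0.15. Noise on the horizontal axis that is independent between genes is argued against, since the lowest of 100 slopes simulated with equal effects was 0.934. Noise that many genes share on an array was not simulated, and the jackknife standard error of the slope over arrays was 0.080. The array that stands apart does not account for it, since the slope without Dex+E2 replicate 2 was 0.642, and a ceiling of the array signal is argued against by a slope of 0.504 (jackknife standard error 0.140) in the 98 Dex-higher genes of lower level. RNA or Dex carried into the E2 samples, open above, could lower this slope too, through the baseline with E2 alone, and was not separately tested here. How far a share of RNA as low as that implied by Dusp1 or Rgs2 would lower it was not worked out. A deviation common to both untreated arrays could also lower it, through the Dex effect without E2, and cannot be told apart in this design. A biological effect of E2 on the Dex response stays open too and was not tested, since no group here varies a dose or blocks a receptor.

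Dex+E2 replicate 2 stood apart from the other arrays, and leaving out its partner gave 608 genes against untreated. A wrong label is argued against: over the genes changed with Dex alone its slope on the Dex effect was 0.894 of that of replicate 1, and over 5 genes raised by E2 and higher with E2 than with Dex its median difference from Dex was 1.3 times that of replicate 1. A distortion that depends on signal level is not enough, since the standard deviation of its difference from replicate 1 was 0.187 with a smooth trend on level removed, above the 0.131 to 0.151 of the other pairs. Why it differs stays open, and no biological explanation was tested.

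With 4 arrays against 4 in a 2-group model, 1 of the 35 splits of the 8 arrays, the real one, gave as many as 333 genes. The highest of the others gave 9. This argues against chance for the Dex effect, but 35 splits are too few to exclude it. Every other split also puts Dex arrays on both sides, which widens the spread within its groups and lowers its count. For the E2 effect chance cannot be excluded in this way: the real split gave 9 genes and 2 of the 35 gave as many, the highest other, 333, being the split by Dex, which is a structure of the samples, while the 33 splits by neither hormone gave 0.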

How the results depend on the processing

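The alternatives in this part were planned before the data were examined, except the list tests without Dex+E2 replicate 2, those with an estimated correlation and dim genes left out, and the block with crossed numbers; further ones added after seeing the data, used elsewhere in the text, are named with the methods. Of 1068 values of named genes under settings that keep every array, 1038 kept their sign and their side of the threshold, 17 lost and 9 gained the call, 4 others moved by over a standard error, and 0 turned direction past the threshold; without 1 array in turn, 955 of 1088 kept it and 118 lost it. The number of arrays limits what can be called.

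Testing every row of the table gave 415 of 45101 probe sets for Dex and 617 for the mean Dex effect, which are not counts of genes. A trended and robust prior gave 35 for E2, 9 for Dex+E2 against Dex, 4 for the interaction and 63 for the mean E2 effect. A second quantile normalization gave 6 for Dex+E2 against Dex and 2 for the interaction, and array weights 4 for Dex+E2 against Dex. A fold of at least 1.5 left 156 for the mean Dex and 22 for the mean E2 effect, and the 2-group model gave 9 for the latter. With only the 4 arrays compared the counts were 171 for Dex+E2 against untreated, 1 against Dex and 23 against E2. Beyond the stricter fold, the fewer arrays and the larger number of rows, the cause was not tested.

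Replicate numbers were not shown to pair the samples: the replicate differences correlated at 0.19, 0.35 and 0.27 among untreated, Dex and E2 and at -0.26, -0.07 and -0.16 between these and Dex+E2. With the replicate number as a block the counts were 265 for Dex, 17 for E2, 251 for Dex+E2, 3 against Dex, 82 against E2 and 1 for the interaction. Under this block Chac1 with Dex (adjusted p = 0.0580) and Il6ra and Pdk4 with E2 (0.0681 and 0.0698) were no longer past the threshold, and no other named gene lost its call. With the Dex+E2 numbers crossed in the block, chosen after seeing the data, the counts were 33 for E2, 10 for Dex+E2 against Dex, 310 against E2 and 2 for the interaction.

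Leaving out 1 array at a time gave 131 to 325 genes for Dex, 2 to 37 for E2, 114 to 608 for Dex+E2, 0 to 81 against Dex, 31 to 858 against E2, 0 to 20 for the interaction, 239 to 840 for the mean Dex and 2 to 90 for the mean E2 effect, 1 to 24 genes shared by Dex and E2, and slopes of 0.559 to 0.654 for Dex and 0.514 to 0.666 for E2. The highest counts came without Dex+E2 replicate 1 for all comparisons of that group. A group left with 1 array adds nothing to the estimated spread, so such counts leave out that array's own deviation. Leaving out either Dex+E2 array also removes the pair with the widest spread, an SD of 0.197, from the estimate. That bears on comparisons that do not use this group as well.

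With an estimated correlation the lists past camera fell from 8 to 1 for Dex, from 3 to 0 for E2, from 8 to 1 for Dex+E2 and from 1 to 0 for the interaction. Without Dex+E2 replicate 2 they were 7, 3, 5 and 1, and with both changes 1, 0, 1 and 0. With fry the lists past the threshold were 7 for Dex, 2 for E2, 8 for Dex+E2 and 1 for the interaction. For E2 they were glucocorticoid targets and circadian clock genes, both at a fry adjusted p = 0.0424. Over the 60 list tests of these comparisons, fry lost 7 calls and gained 5. A second quantile normalization lost 3 and gained 0, and leaving out dim genes lost 3 and gained 4. With dim genes left out, 3 lists passed camera for the interaction, the added ones being circadian clock (adjusted p = 0.0479) and epithelial (0.00471) genes. With an estimated correlation as well, the lists past camera were 1 for Dex, 0 for E2, 1 for Dex+E2 and 0 for the interaction. There these 2 lists were both at adjusted p = 0.267. Losses under an estimated correlation do not come from its size alone. For the clock list with E2 it was -0.0080, below the preset 0.01, yet camera's unadjusted p went from 0.000381 to 0.0184.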

Other observations

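The direct comparison of E2 with Dex was chosen after the other results were seen, as were the genes named in this part.

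Compared directly, E2 and Dex left 210 genes at different levels (limma, Benjamini-Hochberg adjusted p under 0.05), 98 higher with E2 and 112 higher with Dex. The E2 level minus the Dex level was -3.0 ± 0.22 log2 units for Rgs2, -2.30 ± 0.14 for Dusp1, -2.17 ± 0.19 for the vasodilator peptide gene Adm and -1.90 ± 0.17 for Lcn2. On the other side stood Tmem86a, 2.18 ± 0.18 higher with E2, Bnc1, 1.61 ± 0.13, Zfp52, 1.59 ± 0.13, the nuclear non-coding RNA gene Neat1, 1.53 ± 0.11, the transcription factor gene Klf3, 1.17 ± 0.093, and the kinase gene Pim1, 0.98 ± 0.089. Such differences include falls with Dex. Klf3 stood at 9.81 in untreated cells, 8.82 with Dex and 10.0 with E2, and Neat1 at 8.43, 7.57 and 9.10. Neither was called with E2 alone. Of the 19 genes called with E2, 5 were higher with E2 than with Dex in this test: Bnc1, Pim1, Tmem86a, Ttpa and Zfp52.

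Genes whose mean E2 effect passed without a call for E2 alone included Celsr1, a planar cell polarity cadherin, 0.99 ± 0.11, the proteasome-linked gene Midn, 0.96 ± 0.12, the actin-binding gene Synpo, 0.92 ± 0.11, and the angiogenic factor gene Vegfa, 0.70 ± 0.083 (limma, Benjamini-Hochberg adjusted p = 0.00785, 0.0103, 0.0103 and 0.0103). For these 4 genes the E2 effects without and with Dex were 0.78 and 1.21 for Celsr1, 0.93 and 0.98 for Midn, 0.93 and 0.92 for Synpo, and 0.62 and 0.79 for Vegfa. Their shared sign is favoured by the choice of genes on the mean of these effects.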
